A study of Caenorhabditis elegans with 2 samples.

How the data were processed

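The data are peak lists from chromatin immunoprecipitation with sequencing of tagged UNC-62 in mixed-stage embryos, whole organisms, of a transgenic C. elegans strain. Per the labels, the 2 libraries are biological replicates 1 and 2 of 1 group, made from separate biosamples. The labels give the antibody's target as UNC-62 and the factor as the tagged protein, and which part of the fusion the antibody bound is not given in the sources used here. No control library is among the samples, and the authors used a control file in peak calling, per the deposited descriptions of the files.

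There are 8 lists in narrowPeak format: replicate 1, replicate 2, a pooled list and an IDR-thresholded list, each on the builds ce10 and ce11. Per the deposited descriptions, each replicate's list holds peaks and background for IDR and came from that replicate's alignments and a control, the pooled list from both replicates' alignments and a control, and the IDR list from the pooled list and both replicate lists. The names of the aligner, the peak caller and the IDR threshold are not given in the sources used here. Column 7 holds a peak signal that the authors' caller gave each peak, used here only to rank and describe peaks within a list, since its size is not comparable between lists. Column 9 holds the −log10 q of each peak as the authors deposited it. In the IDR list 1173 of the 2754 peaks (42.6%) share its highest value, so peaks were ranked by signal. Library depth is not given in the sources used here, so it is unknown how depth limits the weaker peaks, and a gene with no peak cannot be read as free of UNC-62. Most peaks have 1 fixed width (376 bp for 86.9% of the IDR list), so edges are less exact than summits. The ce11 list of replicate 2 has 30000 peaks and a median width of 370 bp, unlike the 29478 and 376 bp of its ce10 list, and the reason is not given in the sources used here.

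Coordinates are on ce11 and 1-based. Chromosome sequences and genes came from the reference of the same assembly (WBcel235) and its Ensembl annotation, release 115, with 19973 protein-coding genes on 6 nuclear chromosomes. No coordinates were converted between builds, and the ce10 lists were used for counts, widths and signals only. The gene start was the outermost annotated start. A gene counted as having a peak when a summit of a nuclear IDR peak lay from 1000 bp upstream to 500 bp downstream of it. The class of a summit was taken in the order coding sequence, 5′ untranslated or other non-coding exon part, 3′ untranslated region, intron, intergenic. Classes used protein-coding genes only, so intergenic sequence can include non-coding RNA genes and pseudogenes.

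Replicates were compared by overlap of at least 1 bp between the IDR list and the N strongest peaks of each replicate, N being the number of IDR peaks, with 100 circular shifts of 1 list as background, and by the correlation of signals across peaks. Summits were compared with genome shares by two-sided exact binomial tests, and gene classes and lists by two-sided Fisher's exact tests. The 20 gene lists were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Each list was written down before the data were examined, and 3 members over all lists had no gene of that symbol in the annotation. Motifs were searched on both strands within 50 bp of a summit and in windows of the same width 500 bp to each side. Centre and flank were compared with the exact McNemar test, for which 1 flank per peak was drawn at random, and 8 fixed motifs were adjusted together. Hexamers were tested by Fisher's exact test on windows. The relation of TGACAG to signal was tested with 100000 permutations. A p from such tests covers counting error over peaks or genes, not the spread between embryo cultures, since the IDR list is 1 list made from both replicates.

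The genes named follow a rule fixed before the data were examined: unc-62, ceh-20 and all Hox genes whatever their values, the genes of the 12 strongest IDR peaks (those whose window holds the summit, or else the gene around it, or else the nearest start), and up to 3 members of each list with the strongest peaks. Genes named outside the rule are said to be so in the closing section.

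The alternatives tried were other windows around gene starts, the stronger part of the IDR list, the N strongest pooled peaks, the N strongest peaks of each replicate alone, other definitions of overlap, other widths of the central window, other motif backgrounds, gene lists matched on the distance to the upstream gene (10000 draws), circular shifts of the peaks (1000), and genes of operon-like position left out. Backgrounds matched on GC content and lists tested without peaks that hold GAGAGA were added after seeing the data.

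The tests were checked on simulated data. With summits at random positions, 0.05 lists per run of 20 passed on average, and a list of 33 genes of which 20 were given a summit passed in 100% of runs. The random summits were placed independently of each other and of coding sequence. This check therefore does not cover calls that come from the crowding of real summits or their avoidance of coding sequence. With no motif put in, 0 of 2080 hexamers were called, and a hexamer put into 10% of windows ranked 1, with 8 hexamers called in all, so a count of enriched hexamers can exceed the number of separate sites. The paired motif comparison recovered 9.81 of 10 percentage points put in. In these motif checks the mock centres and flanks all came from sequence away from the summits. They therefore do not cover calls that come from the GC content of real centres (45.8%) and flanks (35.0%). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.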

Results

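Chromatin immunoprecipitation with sequencing was used to map where UNC-62 sits in the genome of Caenorhabditis elegans embryos. UNC-62 is a TALE-class homeodomain transcription factor, the worm member of the Meis/Prep family, and it acts with PBC-class homeodomain partners and with Hox proteins. The worms carried a transgene that encodes UNC-62 fused to green fluorescent protein, and the material was whole mixed-stage embryos. There was 1 group with 2 biological replicates and no second condition, so the comparisons are between replicates, between parts of the genome and between groups of genes. The authors' list of peaks that passed their irreproducible discovery rate (IDR) step held 2754 peaks on build ce11, of which 2732 lay on the 6 nuclear chromosomes and 22 on the mitochondrial genome. The replicate lists, which the authors made as peaks and background for the IDR step, held 21749 peaks for replicate 1 and 30000 for replicate 2. Read counts per library were not given in the sources used here, so the depth is unknown. Intervals below are exact binomial 95% intervals and cover counting error over peaks or genes only.

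The strongest UNC-62 peak in the embryo lay beside ceh-20, the gene of a PBC-class homeodomain partner (WBGene00000443). It covered chromosome III 6978937 to 6979388 on ce11, with its summit in intergenic sequence 736 bp upstream of the gene start. Its signal in the authors' IDR list was 973, and it ranked 2 in the list of replicate 1 and 1 in that of replicate 2. The peak ranked 2 lay inside unc-62 itself (WBGene00006796), at chromosome V 4499189 to 4499824, with a signal of 948 and a summit in an exon part without coding sequence. That summit lay 2090 bp downstream of the outermost annotated start and 63 to 224 bp downstream of the starts of 4 shorter transcripts. The peak ranked 3 (signal 756) lay in intergenic sequence 5993 bp upstream of unc-62, at 4491237 to 4491660.

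The gene unc-62 itself had 9 summits inside its annotated body and 18 within 20 kb, while no summit fell in the window from 1000 bp upstream to 500 bp downstream of its outermost start. The peaks ranked 6 and 12 shared 1 interval, chromosome V 4507745 to 4508537, in an exon part of unc-62 that carries no coding sequence in the annotation. Other peaks among the 12 strongest were nearest to casc-3 (signal 710), to ttr-17 of the transthyretin-like family (709), to M106.2 (598) and to ndx-1 of the nudix hydrolase family (509). The peak ranked 8 (signal 618) was intergenic, 145 bp upstream of tlp-1, which encodes a zinc finger transcription factor. The peak ranked 10 (552) was in an intron of Y111B2A.12. The peak ranked 7 (signal 638, chromosome III 7559874 to 7560219) was nearest to the start of lgc-12, a ligand-gated ion channel gene, and lay 4376 bp downstream of the start of the Hox gene ceh-13.

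**Figure D1:**
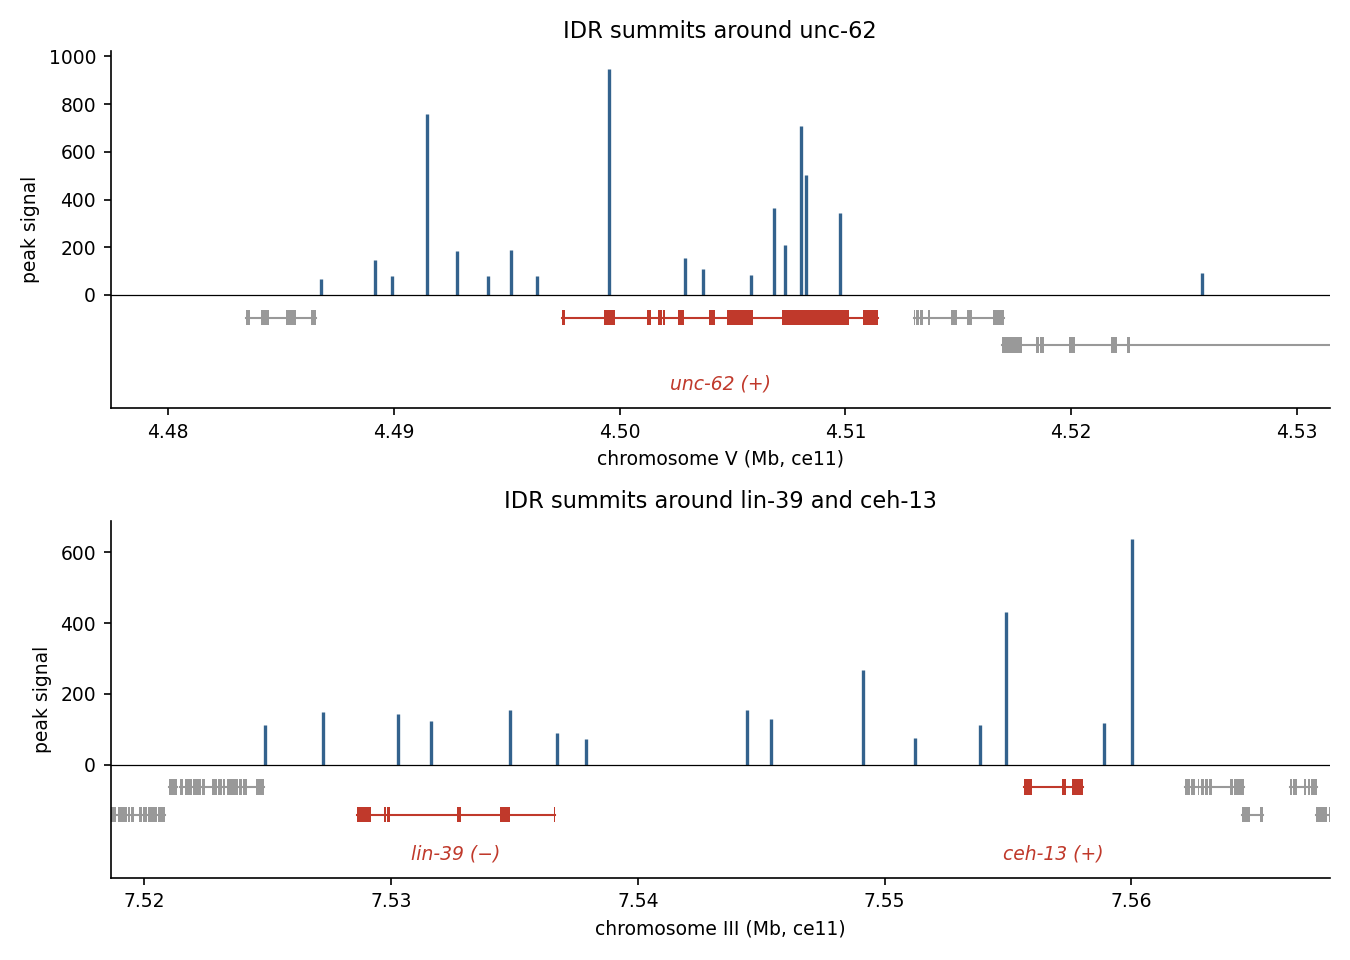
IDR peak summits around unc-62 on chromosome V and around the Hox genes lin-39 and ceh-13 on chromosome III (x axis, position in Mb on ce11; y axis, peak signal in the authors' IDR list; bars, single summits; boxes, annotated exons, with the named genes in red, genes on the plus strand above and on the minus strand below). The unc-62 region held 18 summits, with signals up to 948, and the strongest summit beside ceh-13 had a signal of 638.

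Of the 6 Hox genes, 3 had a summit at their start and 3 had none within 20 kb. The anterior gene ceh-13 (labial class) had the strongest, with a signal of 430 and a summit 736 bp upstream of the start, at chromosome III 7554717 to 7555156. The mid-body genes mab-5 and lin-39 had weaker ones, with signals of 102 (897 bp upstream) and 88.3 (97 bp upstream). The mab-5 gene also held 4 summits in its body and lin-39 held 3, and 12 summits lay within 20 kb of ceh-13. No summit lay within 20 kb of egl-5, nob-1 or php-3, the posterior members. The lin-39 peak was uneven between replicates, with a rank of 916 in replicate 1 and 6282 in replicate 2.

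The 2 replicates shared most of their strong peaks. Of the IDR peaks, 89.1% (87.9 to 90.3) were overlapped by at least 1 bp by one of the 2754 strongest peaks of replicate 1, and 80.5% (79.0 to 82.0) by one of the 2754 strongest of replicate 2. The IDR list was made from both replicates, so these shares are partly built in, unlike the direct overlap that follows. Of the 2754 strongest peaks of replicate 1, 72.1% (70.4 to 73.7) overlapped the 2754 strongest of replicate 2, against 2.65% on average and 3.38% at most in 100 circular shifts along the chromosomes. Across the 2725 IDR peaks found in both full lists, Spearman's rho between the replicates' signals was 0.620 and Pearson's r of log2 signal was 0.690. These are correlations across peaks, which are not independent replicates, and they carry no p. The peaks at ceh-20 and ceh-13 were near the top in both replicates (ranks 2 and 1, and 24 and 22). The IDR list was identical to the 2754 strongest peaks of the pooled list, with 2754 shared intervals, so it holds peaks that ranked high on both replicates' reads together.

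**Figure D2:**
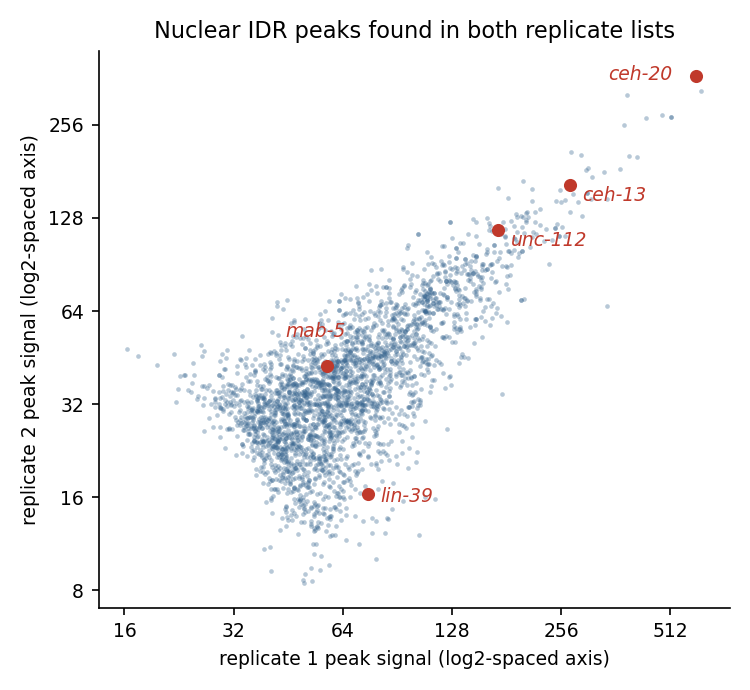
Signal of each nuclear IDR peak in replicate 1 (x axis) and replicate 2 (y axis), both as the authors' peak signal on log2-spaced axes; points are single peaks, and red points are the strongest peaks at the starts of 5 named genes. The peak of ceh-20 ranks 2 in replicate 1 and 1 in replicate 2, whereas that of lin-39 ranks 916 and 6282.

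UNC-62 peaks lay mostly outside coding sequence. Intergenic sequence, meaning outside protein-coding genes, held 65.8% of the 2732 nuclear summits (64 to 67.6) but made up 37.3% of the nuclear genome. Introns held 29.5% of summits against 33.1% of the genome. Coding sequence held 0.988% of summits, 27 in all, against 24.6% of the genome, and 3′ untranslated regions held 0.549% against 3.32%. The window from 1000 bp upstream to 500 bp downstream of a protein-coding gene start held 36.9% of summits (35.1 to 38.7) against 26.4% of the genome, a ratio of 1.40 (two-sided exact binomial test, p = 2.1e-33). The median distance from a summit to the nearest gene start was 1402 bp, against 1655 bp for 10000 random positions. With the narrower window of 500 bp upstream to 200 bp downstream the ratio was 2.07. Both ratios take the whole genome as background, including the coding sequence that summits avoided. Intergenic sequence as a whole had a ratio of 1.76. How much of the excess at gene starts comes from the avoidance of coding sequence was not tested.

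A larger share of genes on X than on the autosomes had a summit at the start. A summit lay in the window of 1234 of 19973 protein-coding genes (6.18%). On X they were 238 of 2731 genes (8.71%) and on the 5 autosomes 996 of 17242 (5.78%), an odds ratio of 1.56 (95% interval 1.35 to 1.81, Fisher's exact test, two-sided, p = 1.5e-08). The autosomes also differed from each other, from 18.4 IDR peaks per Mb on V to 31.7 on I, against 36.3 on X. Shares of genes were not compared between X and single autosomes. On the autosomes, genes in the middle of 3 equal parts of each chromosome had a summit more often than those in the outer parts, 454 of 6570 (6.91%) against 542 of 10672 (5.08%), with an odds ratio of 1.39 (1.22 to 1.58, Fisher's exact test, p = 7.5e-07). Genes are not independent, since neighbours can share a summit. With the stronger 1377 peaks of the IDR list the count of genes was 572.

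Genes of body wall muscle and of the ribosome had UNC-62 peaks at their starts far more often than other genes. Of 33 muscle genes, 19 had a summit in the window (57.6%, odds ratio 20.9, 10.5 to 41.0). They included unc-112, a kindlin of the muscle attachment sites (signal 289, 431 bp upstream), pat-10, the body wall troponin C (188, 130 bp downstream, in a 5′ untranslated or other non-coding exon part), and unc-60, an actin depolymerising factor (171, 367 bp upstream). Of 81 ribosomal protein genes, 45 had a summit (55.6%, odds ratio 19.7, 12.6 to 30.4), among them rpl-3 (signal 295, 268 bp upstream), rpl-12 (231, 51 bp upstream) and rpl-15 (225, 355 bp upstream). These and all list tests were two-sided Fisher's exact tests adjusted by the Benjamini-Hochberg method over 20 lists fixed before the data were examined, and the adjusted p was 2.2e-14 for muscle and 5.4e-32 for the ribosomal proteins. The muscle odds ratio was 11.8 with the strongest peaks of replicate 2 alone, where 14 of the 33 genes had a summit. Against genes of matched GC content the ribosomal protein odds ratio was 12.8.

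Genes of Wnt signalling and cell migration were a further group with more summits than other genes, 9 of 32 (28.1%, odds ratio 5.98, 2.90 to 13.1, adjusted p = 0.00039 by Fisher's exact test). They included lin-17, a Frizzled receptor (signal 187, 645 bp upstream), cwn-1, a Wnt ligand (183, 451 bp upstream), and pry-1, an Axin (174, 507 bp upstream). With a window reaching 2000 bp upstream, 15 of the 32 had a summit, with an odds ratio of 9.11.

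The Hox list passed the test with 3 of 6 genes (50%, odds ratio 15.2, 3.45 to 67, adjusted p = 0.012 by Fisher's exact test). It did not with the window of 500 bp upstream to 200 bp downstream, where 1 gene was left, nor with circular shifts of the peaks, nor with the strongest peaks of replicate 2 alone or the peaks without GAGAGA, each of which left 2 genes. Its adjusted p over the settings ran from 0.012 to 0.476 (Fisher's exact test at both ends). The TALE homeobox list, with ceh-20 and ceh-40 having a summit among 5 genes (40%), did not pass (odds ratio 10.1, Fisher's exact test, adjusted p = 0.084). Its member unc-62 counted as having none, since none lay in the window of its outermost start, although 9 lay in its body. The list passed with the window reaching 2000 bp upstream, where 3 genes had a summit, and with the stronger peaks. In that wider window unc-62 was added, by a summit 1139 bp upstream. The adjusted p of the list ran from 0.014 to 0.45 (Fisher's exact test at both ends). The ceh-40 peak was small (signal 95.2), 28 bp downstream of the start in a 5′ untranslated or other non-coding exon part.

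Histone genes had a summit in 13 of 81 cases (16%, odds ratio 2.92, 1.68 to 5.42, adjusted p = 0.0044 by Fisher's exact test). The windows of these 13 genes held 9 peaks, so some genes shared a summit and the genes are not independent counts. Examples were his-37 (signal 290, 94 bp upstream) and the divergent pair his-67 and his-68, which share a peak (209). Against genes of matched GC content the odds ratio was 1.48 and did not pass, nor did that of 2.24 with replicate 2 alone or the ratio of shares of 3.06 against circular shifts. Histone genes occur in near-identical copies whose reads cannot always be placed, so single members are uncertain.

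Chemoreceptor and F-box genes were the groups with fewer summits than other genes. Among 1277 chemoreceptor genes, 10 had a summit (0.783%, odds ratio 0.113, 0.0642 to 0.218, adjusted p = 4.7e-23 by Fisher's exact test), the strongest at sre-23 (signal 147), srh-2 (114) and srh-17. Among 322 F-box genes, 3 had one (0.932%, odds ratio 0.141, 0.0571 to 0.471, Fisher's exact test, adjusted p = 1.7e-05), namely fbxb-88, fbxa-90 and fbxb-85, with signals of 105, 81.0 and 60.5. The chemoreceptor odds ratio was 0.0636 with the window of 500 bp upstream to 200 bp downstream and 0.075 with the stronger peaks, and the F-box odds ratio was 0.0929 with the strongest peaks of replicate 1 alone.

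The remaining lists did not pass the test. A summit was found at 4 of 28 panneuronal genes (Fisher's exact test, adjusted p = 0.166), among them syd-2, which encodes a liprin of the presynaptic active zone (signal 117), unc-18 (90.9) and egl-3 (65.3). It was found at 6 of 44 epidermal genes (exact test, adjusted p = 0.116), among them spc-1, the alpha spectrin gene (204), the alpha catenin gene hmp-1 (94.3) and dpy-10 (77.6). It was found at 2 of 37 neuronal fate factors, unc-37 and zag-1, which ranked 7699 and 4874 in replicate 2, and at 0 of them with the strongest peaks of that replicate alone. It was found at 2 of 17 genes of the M lineage and sex muscle (ceh-20 and mab-5), 2 of 53 germline genes (mex-1 and cgh-1) and 1 of 38 early embryonic fate factors (sys-1). Among collagens 4 of 156 had one, with signals of 78 at col-38, 75.7 at col-185 and 71.3 at col-85, and the exact test gave an adjusted p of 0.129. Among nuclear hormone receptors 18 of 269 had one, led by nhr-35 (240), nhr-1 (152) and nhr-32 (152), and among the ceh homeobox genes 5 of 63, with ceh-38 (190) after ceh-20 and ceh-13. No summit lay at the starts of 24 pharynx genes, 33 intestine genes or 6 vitellogenin genes, counts of 0 whose exact intervals reach up to 14.2%, 10.6% and 45.9%. Panneuronal (8 of 28), epidermal (10 of 44) and collagen genes (6 of 156, fewer than other genes) passed with the window reaching 2000 bp upstream, so that 11 lists passed with it and 7 with the window used elsewhere.

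**Figure D3:**
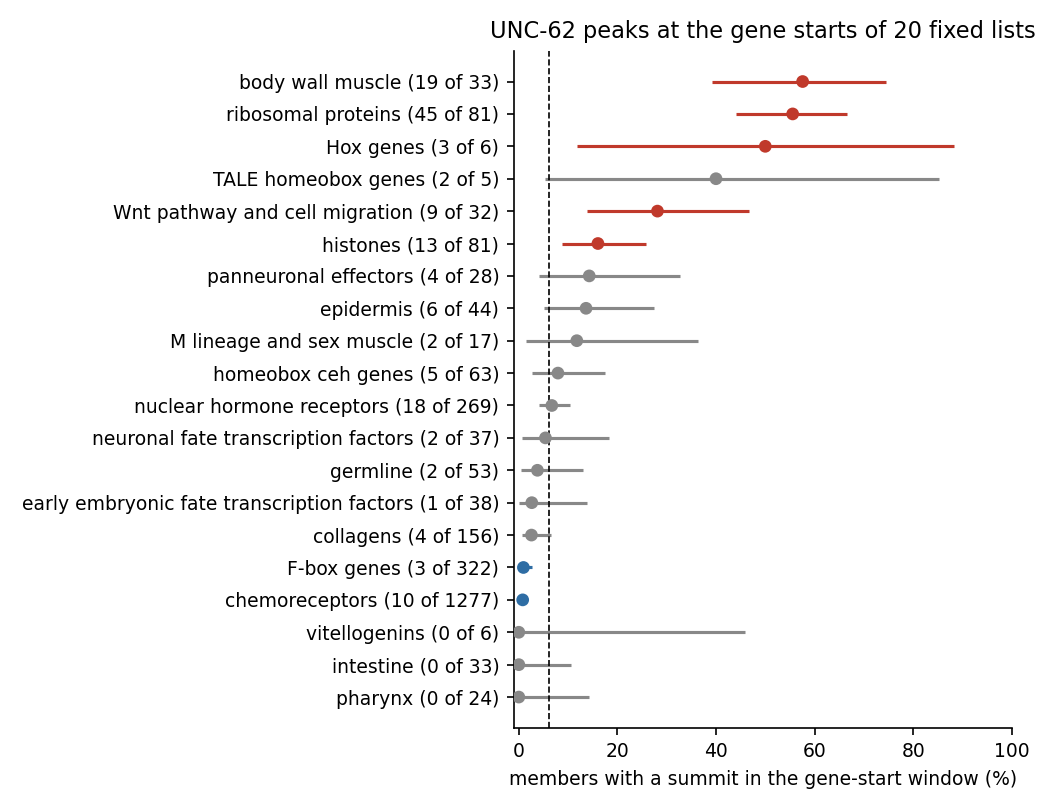
Share of each fixed gene list with an IDR summit from 1000 bp upstream to 500 bp downstream of the gene start (x axis, percent of members; points, share; lines, exact binomial 95% interval; dashed line, 6.18% of all protein-coding genes; red, higher and blue, lower at an adjusted p under 0.05). Body wall muscle (57.6%) and ribosomal protein genes (55.6%) stand far to the right, and chemoreceptors (0.783%) and F-box genes (0.932%) lie below the dashed line.

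The Meis core site was enriched under UNC-62 summits. TGACAG, on either strand, was present within 50 bp of the summit in 350 of 2732 nuclear peaks (12.8%, 11.6 to 14.1), against 3.4% of windows 500 bp to the sides, a ratio of 3.76 (exact McNemar test of the centre against 1 flank per peak, two-sided, adjusted p = 8.3e-39). The composite site TGATTGACAG, with at most 1 mismatch, in which a PBC and a Meis protein can sit side by side, was present in 3.59% against 0.622%, a ratio of 5.76 (exact McNemar test, adjusted p = 4.1e-13). The peak upstream of unc-62 and the peaks nearest to casc-3, ttr-17 and M106.2 carried the composite site. Those nearest to casc-3, ttr-17 and M106.2 also carried TGACAG. The peak upstream of unc-62 did not, so the mismatch of its composite site lay in the TGACAG part. The ceh-20 peak carried neither the composite site nor TGACAG. Of the PBC-Hox sites, TGATTGAT was present in 3.4% against 0.549% and TGATTTAT in 2.67% against 0.824% (exact McNemar test, adjusted p = 3.9e-16 and 6.1e-08), while TGATTAAT, at 0.805% against 0.512%, missed the threshold (adjusted p = 0.0501). Against windows shuffled by a first-order Markov chain the ratio was 1.92 for TGACAG and 2.65 for the composite site.

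The enriched hexamer found in the largest share of peaks was not a homeodomain site. GAGAGA was present within 50 bp of the summit in 872 peaks (31.9%, 30.2 to 33.7) against 5.82% of flanks, a ratio of 5.48 (exact McNemar test, adjusted p = 4.6e-137). The E box CANNTG was present in 49.4% against 31.1% (exact McNemar test, adjusted p = 1.2e-47), and the GATA site WGATAR in 23.1% against 20.5% (adjusted p = 0.035). The WGATAR call was lost with a central window of 100 bp to each side and with the stronger peaks (ratio 1.1 in both). Of 2080 hexamers merged with their reverse complements, 881 were enriched and 535 depleted (Fisher's exact test on windows, Benjamini-Hochberg). Among the enriched hexamers GAGAGA had the lowest p, and ACGCAG, present in 14.2% of centres and 1.72% of flanks, had the highest ratio (8.28) among enriched hexamers found in at least 50 centres. The centres had a GC content of 45.8% and the flanks 35%. Against non-coding positions of matched GC content outside peaks, a background chosen after seeing the data, 394 hexamers were enriched, the ratio was 3.89 for TGACAG, 8.91 for the composite site and 3.54 for GAGAGA. The ratio of ACGCAG fell to 2.72 there, under those of TGACAG and GAGAGA. The same background gave 10.3 for TGATTGAT, 10.4 for TGATTTAT, 1.68 for WGATAR and 1.41 for the E box, and TGATTAAT passed (0.805% against 0.183%).

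**Figure D4:**
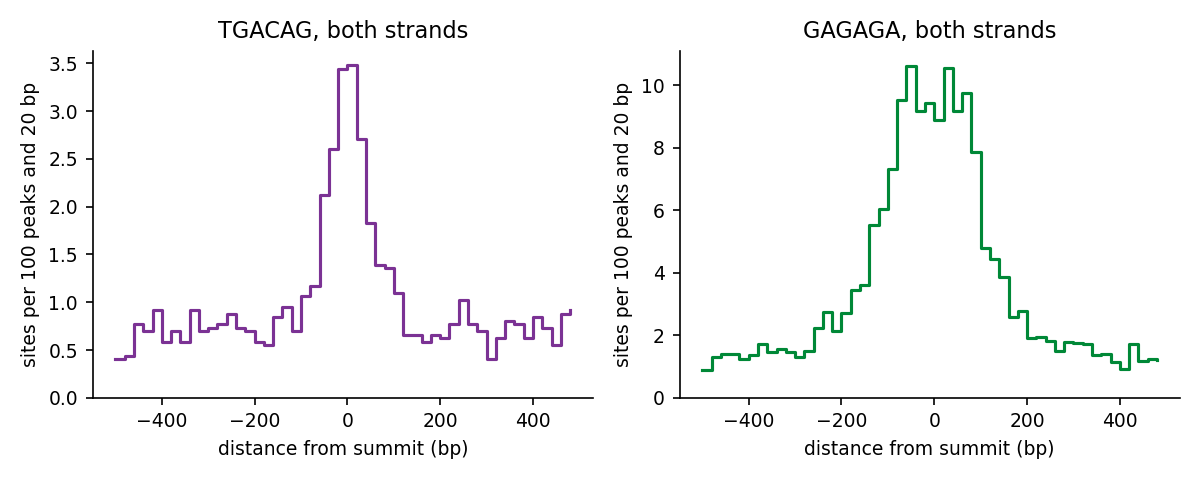
Occurrence of TGACAG and GAGAGA around nuclear IDR summits (x axis, distance from the summit in bp; y axis, sites on either strand per 100 peaks in each 20 bp bin). TGACAG reaches 3.48 sites per 100 peaks in the bin at the summit, and GAGAGA reaches 10.6 over a broader region.

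Stronger peaks carried TGACAG more often. From the strongest to the weakest of 5 equal groups of nuclear peaks by signal, the share with TGACAG was 17.6%, 14.8%, 10.1%, 9.89% and 11.7%, with flank shares between 3.11% and 3.75%. Peaks with TGACAG lay 6.74 percentile points higher in signal on average than peaks without it (55.9 against 49.1, permutation test with 100000 resamples, two-sided, p = 4e-05). The composite site fell from 6.76% in the strongest group to 1.83% in the weakest. GAGAGA showed no such difference that passed the test, at 33.1% in the strongest and 32% in the weakest group (1.62 percentile points, permutation p = 0.171). Among the 1008 summits in gene-start windows alone the difference for TGACAG was 5.61 points and missed the threshold (permutation p = 0.058), and with a central window of 51 bp it was 10.8 points.

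**Figure D5:**
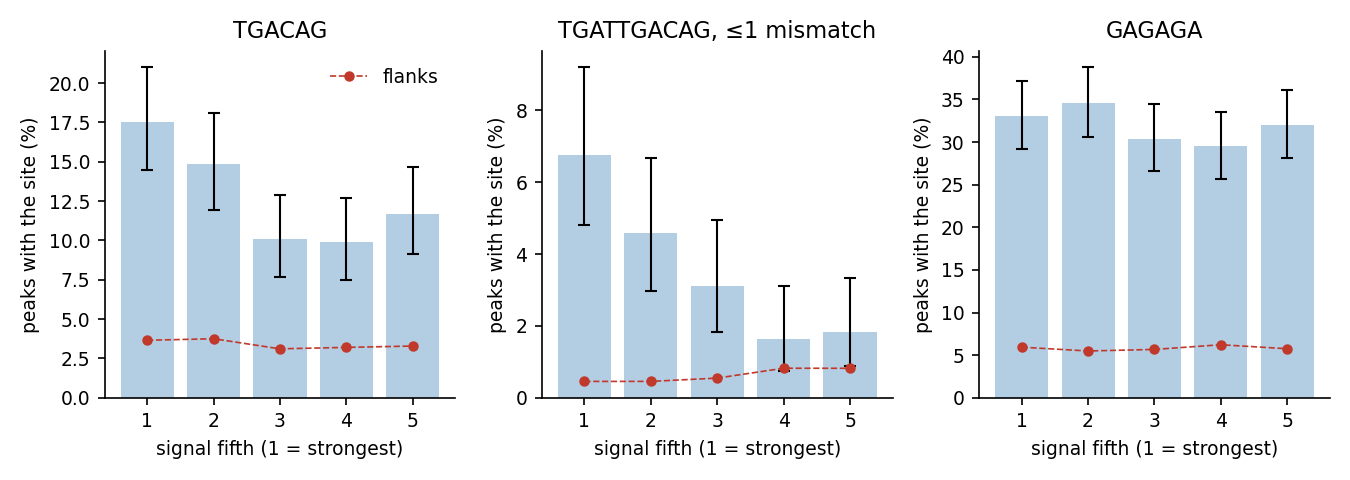
Share of nuclear IDR peaks with TGACAG, with TGATTGACAG at up to 1 mismatch, and with GAGAGA within 50 bp of the summit (y axes, percent of peaks, each panel with its own scale; x axes, signal group, 1 being the strongest; bars, share with exact binomial 95% interval; red points, mean share of the flanks 500 bp away). TGACAG is in 17.6% of the strongest and 11.7% of the weakest group, whereas GAGAGA is in 33.1% and 32%.

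The lists on the older build ce10 gave nearly the same picture. The IDR list held 2756 peaks on ce10 and 2754 on ce11, with 644 on X and 22 on the mitochondrial genome in both. The highest signal was 973 on both builds, and the medians were 94.7 on each. The exception was replicate 2, whose list held 29478 peaks with a median width of 376 bp on ce10 and 30000 with a median width of 370 bp on ce11. Whether that list was cut at this length or made with other settings is not given in the sources used here, so its length and its weaker ranks are uncertain.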

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

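No test in this part was chosen after its result was seen.

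The IDR list held 22 peaks on the mitochondrial genome, above the 3 that a count of 0 allows. The comparisons with genes, sequence classes and motifs left them out, whereas the counts of peaks and the comparisons between replicates and builds included them. They covered 43.3% of its 13794 bp, with signals from 65.1 to 485, and the replicate lists held 22 and 26 such peaks. A candidate explanation is the many copies of mitochondrial DNA in the extract. TGACAG was within 50 bp of the summit in 0 of the 22 peaks (0% to 15.4%), against 0.701% of all windows of that genome. The upper bound lies above the 12.8% of nuclear peaks, so this explanation and binding cannot be told apart with 22 peaks, and no biological explanation was tested.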

How the results depend on the processing

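Matching on GC content and leaving out peaks with GAGAGA were chosen after seeing the data, and the other settings before. No paired analysis was possible because there is 1 group. Leaving out a replicate meant ranking the other one's peaks alone, which cannot be done for the overlap or correlation of replicates. All peaks pass a q of 0.01 and the strongest pooled peaks are the IDR list itself, so those settings moved nothing and say nothing about stability. The signal groups were not split further by strength. Depth is unknown.

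Direction and side of the threshold were kept in all settings run by the ratios for gene starts (1.28 to 2.07), TGACAG (1.92 to 4.27) and the composite site (2.65 to 10.8) and the odds ratios for X (1.46 to 1.65) and chromosome centres (1.35 to 1.51). The same held for the ribosomal protein (9.16 to 27), muscle (8.05 to 23.6), Wnt and migration (4.06 to 9.11), chemoreceptor (0.0636 to 0.155) and F-box lists (0.0929 to 0.2), where circular shifts gave ratios of shares. Where a value below changed, the cause was not tested. Overlap of the IDR list with the strongest peaks of replicates 1 and 2, and of these with each other, was 86.1%, 72.7% and 63.9% with 50% reciprocal overlap, 87.7%, 77.4% and 66.6% with summits within 100 bp, and 99.6%, 93.2% and 62% with 2 times as many peaks per replicate. The stronger 1377 peaks gave 572 genes, which follows from fewer peaks, an odds ratio of 22.7 for TALE genes, now past the threshold, and 0.788 for epidermis, reversed. GC-matched positions gave 394 enriched hexamers against 881. For TGACAG and signal, summits in gene-start windows gave 5.61 points (permutation p = 0.058) and a central window of 51 bp gave 10.8. Of the 6 motifs other than TGACAG and the composite site, 5 passed as reported and 4 with 100 bp to each side or the stronger peaks, where WGATAR did not.

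With the window of 500 bp upstream to 200 bp downstream, odds ratios were 4.32 for Hox genes (no longer past) and 0 for the M lineage (0 of 17, reversed). With 2000 bp upstream, 11 lists passed, with TALE 15.4, panneuronal 4.12, epidermis 3.03 and collagens 0.408 newly past, and nuclear hormone receptors reversed at 0.912. Circular shifts ended the calls of Hox genes (ratio of shares 7.88) and histones (3.06). GC matching ended that of histones (1.48) and made that of collagens (0.277). Without peaks holding GAGAGA the Hox odds ratio was 10.8 (no longer past), and neuronal fate factors (1.23) and nuclear hormone receptors (0.744) reversed. Over the 2 single-replicate rankings, odds ratios were 7.94 to 15.1 for Hox genes and 2.24 to 3.46 for histones (both lost with replicate 2 alone), 1.51 to 3.01 for epidermis (past with replicate 2 alone), 0.195 to 0.523 for collagens (past with replicate 1 alone) and 0.827 to 1.42 for nuclear hormone receptors (reversed with replicate 1 alone). Of 41 named genes with a summit in the window, 32 had one with replicate 2 alone, 38 with replicate 1 alone, 23 in the narrower window and 27 among the stronger peaks.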

Other observations

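The tests chosen only after results had been seen are those of non-coding genes, gene families, crowded genes and pairs of motifs, with the genes named there. Further ones are those of even coverage at unc-62, of motifs at ribosomal, muscle, histone and Wnt genes, and of matched GC content at ribosomal protein genes. Several classes of non-coding RNA genes had a UNC-62 summit within 500 bp more often than in shifted peaks. This held for 72 of 346 snoRNA genes (20.8%, 16.7 to 25.5), against 3.05% on average and 5.20% at most in 100 circular shifts of the peaks. For tRNA genes it was 96 of 612 (15.7%, 12.9 to 18.8; shifted mean 3.25%, highest 5.07%) and for snRNA genes 10.1% (highest 8.53%). Among microRNA genes 22 of 261 had one (8.43%; highest shifted value 8.05%), with the strongest peaks at mir-53 (signal 331), mir-4929 (280) and mir-90 (207). Other ncRNA genes (12.2%; highest 3.83%) and lincRNA genes (11.9%; highest 9.28%) were above the shifts too. Antisense RNA genes were within the range of the shifts (7%; highest 12%). Pseudogenes had fewer than the mean of the shifts, 20 of 2128 (0.940% against 5.69%), and so did piRNA genes (1.56% against 2.32%). Neighbouring genes can share a summit. The snRNA and microRNA counts were close to the highest shifted counts (13 against 11 and 22 against 21 genes). No adjustment was made over the classes. Circular shifts do not keep the summits' avoidance of coding sequence (0.988% of summits against 24.6% of the genome). How much of the excess comes from that was not tested.

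Of 175 gene families with at least 10 members by the prefix of their symbols, 16 passed Fisher's exact test after Benjamini-Hochberg adjustment, 10 with more and 6 with fewer summits at their starts than other genes. Beside the ribosomal families, subunits of the vacuolar ATPase (vha, 6 of 20, odds ratio 6.54, exact test, adjusted p = 0.022) and J-domain proteins (dnj, 7 of 29, 4.85, adjusted p = 0.031) had more. The mig genes, named for cell migration defects, had 5 of 16 (6.93, exact test, adjusted p = 0.035) and the unc genes, named for uncoordinated movement, 28 of 94 (6.57, adjusted p = 7.6e-11). The unc result repeats part of the muscle result, since members with a summit such as unc-112, unc-60, unc-54 and unc-22 are on both lists. C-type lectin genes had fewer (clec, 5 of 240, 0.320, exact test, adjusted p = 0.049).

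The gene with the most summits in its body was unc-62 (9), followed by lsy-22 (7), while egl-27, a chromatin factor gene, cam-1, a Ror-type receptor gene, and sax-3, a Robo-type receptor gene, had 5 each. Within 20 kb of a gene the count was highest for egl-27 (19) and then unc-62 (18), and the median gene had 1. TGACAG and GAGAGA occurred together in 102 peaks, and TGACAG was in 11.7% of peaks with GAGAGA and 13.3% of those without (Fisher's exact test, adjusted p over 5 comparisons 0.305). Peaks with TGACAG were in a gene-start window less often than other peaks, 30.3% against 37.9% (Fisher's exact test, adjusted p = 0.016). Peaks with GAGAGA were less often on X, 18.3% against 26% (Fisher's exact test, adjusted p = 4.2e-05).

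The crowding of peaks around unc-62 may come from extra copies of the tagged transgene in the strain. The pooled list held 38 summits within 20 kb of the gene, at percentile 99.995 of other protein-coding genes, which is what extra copies would give and also what a locus with many UNC-62 sites would give. Coverage raised evenly over the locus would place summits in coding sequence, and 2.63% of the 38 lay there (1 summit, interval 0.0666% to 13.8%) against 9.44% of the sequence. With 38 summits, no count of coding summits could have excluded an even rise in this test (one-sided exact binomial p = 0.459 against 4.72%). An even rise thus cannot be told apart from separate sites. No biological explanation was tested.

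The peaks at ribosomal protein genes may reflect signal at these gene starts that does not rest on the Meis core. TGACAG was within 50 bp of the summit in 0 of the 43 peaks there (0% to 8.22%), at or under the flank share of 3.4% and against 11% of the other 965 peaks in gene-start windows (Fisher's exact test, p = 0.018). GAGAGA was in 9.30% of them and 30.7% of the others (Fisher's exact test, p = 0.0018). TGACAG was in 2 of 19 peaks at muscle genes and 1 of 9 at histone genes. Neither share could be told apart from the flank share with so few peaks (one-sided exact binomial test, p = 0.135 and 0.268). At 10.5% and 11.1%, these shares were near the 10.5% of all peaks in gene-start windows. At Wnt and migration genes TGACAG was in 2 of 9 peaks (one-sided exact binomial test against the flank share, p = 0.0356). No adjustment was made over these gene groups, and peaks in gene-start windows as a whole were above the flank share too. GC content of the window as the whole cause is argued against, since the odds ratio against genes of the same GC decile was 12.8. No biological explanation was tested.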
